A study of Drosophila melanogaster with 4 samples.

How the data were processed

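Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out for γH2AvD, the phosphorylated form of the Drosophila histone variant H2Av that marks DNA damage, in S2 cells, an established Drosophila cell line. The 4 libraries were a γH2AvD ChIP and an input library from wild-type (WT) cells, and the same pair from cells treated with double-stranded RNA against the linker histone dH1 (dH1 RNAi). Per the labels' protocols, 100 µg of double-stranded RNA was added to the dH1 RNAi cells on days 1, 4 and 7 of an incubation of 8 days. All libraries were made from 10 ng of DNA with 15 PCR cycles. The labels give no double-stranded RNA and no incubation time for the WT cells, and the level of dH1 is not given in the sources used here. Each group had 1 library, so no value has a replicate error and no p-value is given for a difference between the conditions.

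Per the submitters' processing notes, Bowtie 0.12.5, FastQC 0.10.1 and the dm3 build were used. Per the file headers, regions were called with the CCAT caller of PeakRanger 1.16 with a sliding window of 500 bp, a step of 50 bp, at least 4 reads in a window, a minimum window fold of 3 and a false discovery rate (FDR) cut-off of 0.1. The 3 deposited region lists compared WT ChIP with WT input, dH1 RNAi ChIP with dH1 RNAi input, and dH1 RNAi ChIP directly with WT ChIP. Per the file headers, reads were extended to 200 bp in the first pair of lists and to 50 bp in the direct list. Each region carries a count of ChIP reads and a count of control reads, deposited as whole numbers with no normalization. Each region also carries an FDR from the caller, which is the deposited p-value type column and was used only to keep regions within the cut-off. In the direct list 3 regions had an FDR above the cut-off and were left out, which left 66. Library totals are not given in the sources used here, so the depth of the libraries is unknown and counts were not scaled by depth. ChIP counts rose with region width across each list (Spearman 0.763 in the WT list, 0.502 in the dH1 RNAi list and 0.470 in the direct list), but not always in proportion to it: a mitochondrial region of 9150 bp carried 544 ChIP reads and another of 700 bp carried 280. Whether a count covers the whole region or a part of it is not given in the sources used here, so counts were not divided by width. The treatment of duplicate reads and of reads that align to several places was not examined here. Regions in repeated sequence may therefore share reads and need not be separate sites.

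The files hold no fold column, so the ratio of ChIP to control reads was computed for each region and replaces the caller's fold planned before the data were examined. A ratio below 1 is possible for a called region because the counts are not scaled by depth. Stricter fold thresholds of 4, 5 and 10 were replaced by a ratio of at least 4/3, 5/3 and 10/3 of the lowest ratio of the list. A count test across libraries was not run, since there was 1 library per condition and the regions were called separately in each list. Gene lists chosen before the data were examined were not evaluated: the gene column of the lists was empty and no annotation of dm3 was used here. Regions are given by dm3 coordinates, counted from 1.

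The sequence classes were fixed before the data were examined. They were chromosome 4, the Het scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet), unplaced sequence (U and Uextra), the centromere-proximal 1 Mb and the telomeric 100 kb of arms 2L, 2R, 3L, 3R and X, the remaining arm sequence, and the mitochondrial genome. Heterochromatic sequence was the sum of chromosome 4, the Het scaffolds, unplaced sequence and the proximal 1 Mb. Named regions were, in each list, the 3 with the highest ratio in each class and the 3 widest, with ties broken by ChIP reads, then width, then coordinate, and the 3 shared regions with the highest WT ratio. Windows of 6 loci with known repeat or chromatin features were also fixed beforehand and are approximate.

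Overlap of at least 1 bp was found with bedtools 2.31.1, and 1000 same-chromosome shuffles gave the overlap of randomly placed lists. For each list, the number of regions per class was also drawn at random 10000 times, with each region falling independently by class length. Shares have exact Clopper-Pearson 95% intervals and count ratios have exact 95% intervals for 2 Poisson counts. All intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Class shares were compared with a two-sided Fisher's exact test, adjusted by the Benjamini-Hochberg method over 8 shares. Such a test compares the lists, not the conditions, and takes each region as independent. For a WT region overlapping more than 1 dH1 RNAi region, the partner with the largest overlap was used. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The code of the overlap step was checked with WT regions shifted by 100 bp, where 100 of 100 were found. The interval of a ratio covered its true value in 95.7% of 2000 Poisson draws at fixed means. These checks bear on the code and not on the data.

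Alternatives tried were the ratio thresholds, merging of neighbouring regions, removal of unplaced sequence, a higher count minimum, other proximal lengths, shares by base pairs, equal list lengths, other overlap rules and width-weighted medians. After seeing the data, limits of 150, 200 and 300 control reads, the 3 regions above the FDR cut-off, the removal of the mitochondrial genome and a stricter pairing of shared regions were added. The split at 200 control reads used throughout was likewise chosen after seeing the data.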

Results

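γH2AvD was mapped by ChIP-seq in WT Drosophila S2 cells and in S2 cells treated with double-stranded RNA against the linker histone dH1, with 1 ChIP and 1 input library per condition. No control double-stranded RNA is recorded for the WT cells, so the treatment itself and a loss of dH1 cannot be told apart. The region lists give the sites called for this DNA damage mark over the input in each condition and those called in the dH1 RNAi ChIP over the WT ChIP. The WT list held 297 regions, the dH1 RNAi list 1563 and the direct list 66. No comparison between the conditions has a replicate, and the library totals, and with them the depth, are unknown. The median region carried 239 ChIP and 94 input reads in the WT list, and 127 ChIP and 125 input reads in the dH1 RNAi list.

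In WT cells γH2AvD regions were densest on chromosome 4, the small and largely heterochromatic chromosome of Drosophila, and near the centromeres. Chromosome 4 held 28 of the 297 regions, or 20.7 per Mb, a share of 9.43% (95% interval 6.36 to 13.3) for 0.801% of the assembly length. The centromere-proximal 1 Mb of the arms held 36 regions (12.1%, 8.64 to 16.4, for 2.96% of the length), and the Het scaffolds, assembled heterochromatin outside the arms, held 26 (8.75%, 5.80 to 12.6, for 5.50%). The proximal regions were uneven between arms, with 14 between 22 and 23 Mb of 2L and 12 in the first 1 Mb of 2R. The first 1 Mb of 3R held 6, and the proximal sequence of 3L and of X held fewer. In 10000 random draws by length share, chromosome 4 held a mean of 2.41 regions and the proximal sequence 8.76. The share of draws with as many regions as observed was at or below 0.0001, the lowest value recorded, in each of these classes. The remaining arm sequence held 194 regions (65.3%) for 67.3% of the length, and unplaced sequence held 12 (4.04%) for 23.1%.

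The highest WT ratios lay on chromosome 4, on a Het scaffold and on 3R. The region at 1047201 to 1048650 of chromosome 4 had 497 ChIP and 79 input reads, a ratio of 6.29 (4.95 to 8.08). At 197051 to 199200 of 2RHet the ratio was 6.27 (4.86 to 8.19), and at 8537501 to 8539100 of 3R, in the remaining arm sequence, 815 ChIP reads over 131 gave 6.22 (5.17 to 7.54). The widest WT region, 2950 bp at 32351 to 35300 of 2LHet, had 722 ChIP reads and a ratio of 5.39 (4.48 to 6.53). By class the median ratio was 4.17 on chromosome 4, 3.96 on the Het scaffolds, 3.04 in the proximal sequence, 2.45 in the remaining arm sequence and 2.24 in unplaced sequence. The single telomeric region of the WT list, at 27877451 to 27878750 of 3R, had 250 ChIP and 78 input reads, a ratio of 3.21, and overlapped no dH1 RNAi region.

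The dH1 RNAi list held 5.26 times as many regions as the WT list and covered 5.43 times the length, 1749 kb against 321.9 kb. At 10/3 of the lowest ratio of each list, the strictest threshold tried, it held 133 regions against 86, or 1.55 times as many, over 171.4 kb against 114.8 kb. That lowest ratio was 0.446 in the dH1 RNAi list, at a mitochondrial region, and 1.10 in the WT list. The lowest nuclear ratio of the dH1 RNAi list was 0.475. The threshold was therefore a lower ratio in the dH1 RNAi list, and no common ratio was applied to both lists. The median width was 950 bp against 1100 bp. Within the dH1 RNAi list the median ratio was 0.921 (interquartile range 0.603 to 1.13), and 931 of the 1563 regions (59.6%) had fewer ChIP than input reads. Within the WT list the median was 2.65 (1.93 to 3.85). Because depth is unknown, each ratio describes regions of its own list, and no direction between the lists is drawn from these medians.

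The whole dH1 RNAi list, shared regions included, was spread over the sequence classes otherwise than the WT list. Unplaced sequence held 376 regions in the dH1 RNAi list against 12 in the WT list, 31.3 times as many, and its share of the list was 24.1% against 4.04% (adjusted p = 9.13e-18, Fisher's exact test). The remaining arm sequence held 1009 regions against 194, with a share of 64.6% against 65.3% (adjusted p = 0.963, Fisher's exact test). Chromosome 4 held 22 regions against 28, and its share was 1.41% against 9.43% (adjusted p = 1.96e-10, Fisher's exact test). Its 12 WT regions with no dH1 RNAi counterpart had a median of 161.5 ChIP reads, against 327.5 at the 16 shared ones. The lowest ChIP count of any dH1 RNAi region was 69, so weaker sites may have gone uncalled and the lower number does not show a loss. By the same exact test, the shares of the proximal sequence (5.25% against 12.1%, adjusted p = 0.000109) and of the Het scaffolds (4.35% against 8.75%, adjusted p = 0.00676) were also lower, although their numbers were higher, at 82 against 36 and 68 against 26. The mitochondrial genome held 5 dH1 RNAi regions and no WT region. These tests compare the lists, not the conditions. They take each region as independent, although many lay close together: merging those under 10 kb apart left 1031 dH1 RNAi and 259 WT regions. The p-values may therefore be too small.

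**Figure D1:**
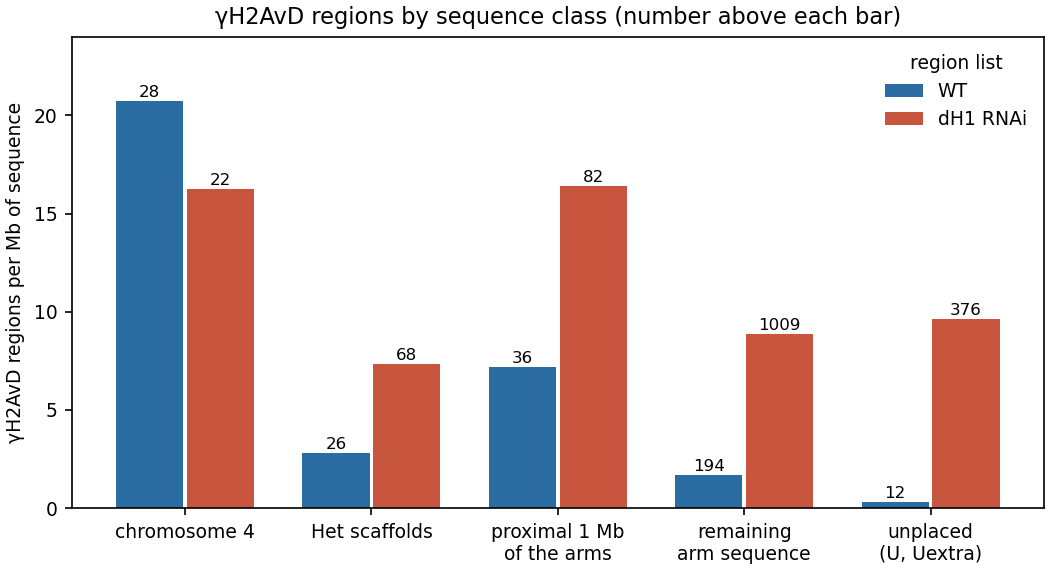
Number of γH2AvD regions per Mb of sequence (vertical axis) in 5 sequence classes, for the WT and dH1 RNAi lists, with the number of regions above each bar. Chromosome 4 is the class with fewer dH1 RNAi regions (22) than WT regions (28), and unplaced sequence goes from 12 to 376.

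Taken as a whole, heterochromatic sequence held 34.3% of WT regions (102; 29.0 to 40.0) and 35.1% of dH1 RNAi regions (548; 32.7 to 37.5), for 32.4% of the assembly length (p = 0.842, Fisher's exact test). This near equality rested on unplaced sequence. Without it, heterochromatic sequence held 90 of 285 WT regions (31.6%) and 172 of 1187 dH1 RNAi regions (14.5%), for 12.1% of the length (p = 1.56e-10, Fisher's exact test).

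Most WT regions were also called after dH1 RNAi, while most dH1 RNAi regions had no WT counterpart. Of the 297 WT regions, 215 (72.4%, 66.9 to 77.4) overlapped a dH1 RNAi region, against a mean of 6.75 and a highest value of 15 in the shuffles. Of the 1563 dH1 RNAi regions, 214 (13.7%, 12.0 to 15.5) overlapped a WT region. The overlap was 31 of 36 WT regions in the proximal sequence, 21 of 26 on the Het scaffolds, 141 of 194 in the remaining arm sequence, 16 of 28 on chromosome 4 and 6 of 12 in unplaced sequence. Absence from a list does not show absence of the mark.

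Each of the 215 shared WT regions was set beside the dH1 RNAi region that overlapped it most, and the dH1 RNAi region had fewer ChIP reads in each pair. The intervals were called separately and differ in width and position, and the pairs used 213 dH1 RNAi regions. The ratio of dH1 RNAi to WT ChIP reads had a median of 0.434 (interquartile range 0.383 to 0.503) and was below 1 at 215 of 215 regions. Input reads of the same pairs had a median ratio of 0.780 (0.687 to 0.886). Divided by the input ratio, the ChIP ratio had a median of 0.562 (0.473 to 0.666) and was below 1 at 213 regions. By class the median over these 215 pairs was 0.532 on the Het scaffolds, 0.544 on chromosome 4, 0.544 in the proximal sequence, 0.587 in the remaining arm sequence and 0.608 in unplaced sequence. In the 191 pairs that covered at least 50% of each other and used each partner once, a choice made after seeing the data, the medians over all classes were 0.430 for ChIP reads, 0.777 for input reads and 0.554 for their quotient. The region at 8537501 to 8539100 of 3R had 305 ChIP and 67 input reads after dH1 RNAi, a ratio of 4.55 (3.48 to 6.02), the highest in the dH1 RNAi list. At the chromosome 4 region with the highest WT ratio the dH1 RNAi ratio was 2.86 (2.17 to 3.81), and at the 2RHet region it was 1.89 (1.40 to 2.56). With library totals unknown, a uniform factor between the libraries is part of each of these ratios.

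**Figure D2:**
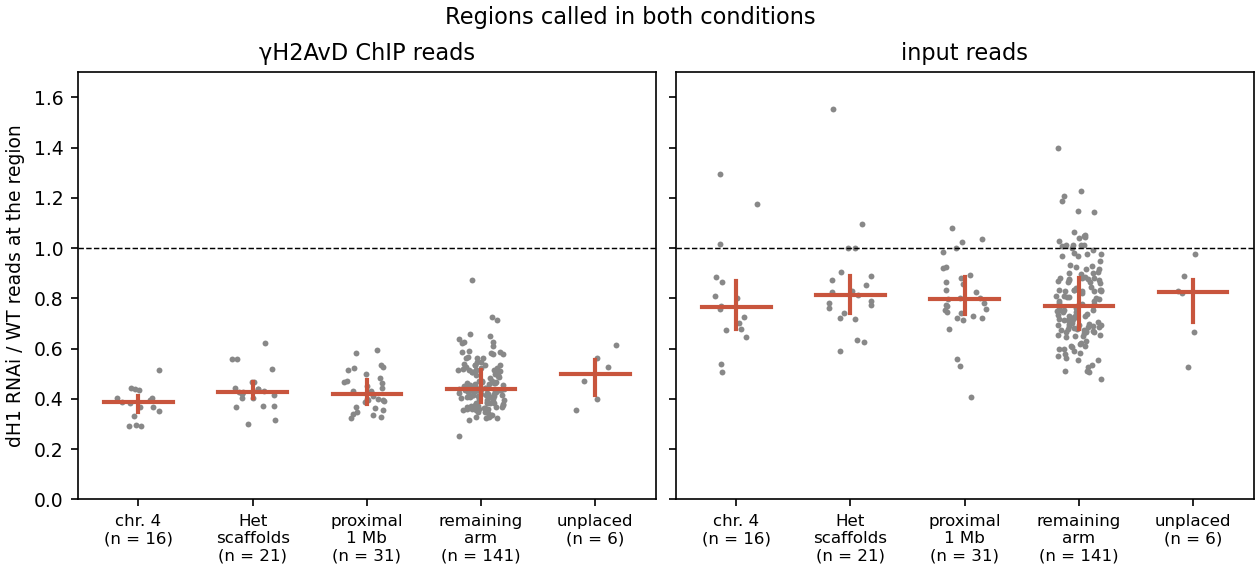
Ratio of dH1 RNAi to WT reads (vertical axis) for the 215 pairs of overlapping regions called in both conditions, for ChIP reads and input reads, by sequence class. Points are regions, horizontal bars are medians and vertical bars are interquartile ranges. All ChIP points lie below 1, around a median of 0.434, and the input points lie around 0.780.

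Many of the dH1 RNAi regions lay in sequence with a high input count. More than 200 input reads were found at 593 of the 1563 dH1 RNAi regions (37.9%, 35.5 to 40.4) and at 7 of the 297 WT regions (2.36%, 0.953 to 4.80). These dH1 RNAi regions made up 322 of 376 in unplaced sequence, 45 of 68 on the Het scaffolds, 26 of 82 in the proximal sequence, 191 of 1009 in the remaining arm sequence, 3 of 22 on chromosome 4 and 5 of 5 on the mitochondrial genome. Their median ratio was 0.572, against 1.07 for the 970 regions at or below 200 input reads. The widest of them, 8100 bp at 2086301 to 2094400 of 2RHet, had 489 ChIP and 764 input reads. Restricted to at most 200 input reads, a limit chosen after seeing the data, the lists held 970 and 290 regions, a ratio of 3.34. The remaining arm sequence then held 818 against 192, unplaced sequence 54 against 9, the proximal sequence 56 against 35, the Het scaffolds 23 against 25 and chromosome 4 19 against 28.

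**Figure D3:**
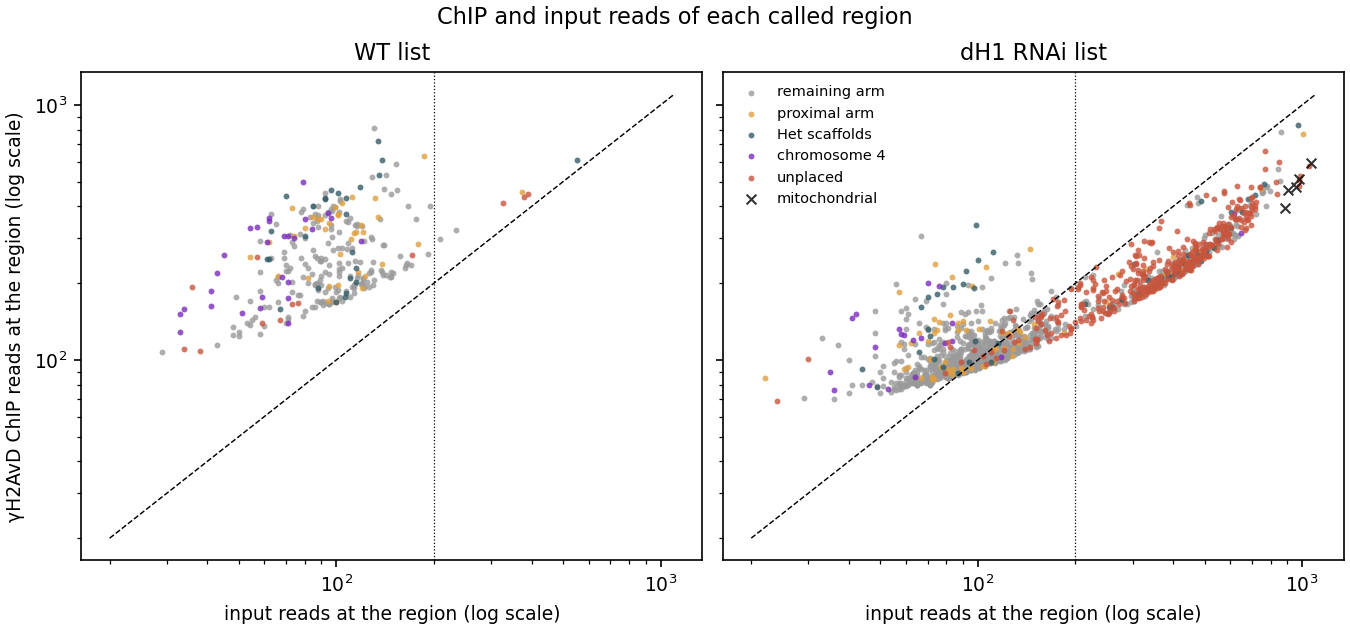
γH2AvD ChIP reads (vertical axis, log scale) against input reads (horizontal axis, log scale) for each region of the WT and dH1 RNAi lists, coloured by sequence class, without the single telomeric region of each list. The dashed line marks equal counts and the dotted line 200 input reads. In the whole lists 593 dH1 RNAi regions, with the telomeric region that is not drawn, and 7 WT regions had more.

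Called directly over the WT ChIP, the dH1 RNAi ChIP gave 66 regions over 93.2 kb, most of them in repeat-rich unplaced sequence. Unplaced sequence held 46 regions, 40 of them on Uextra, and the Het scaffolds held 6, the proximal sequence 3, the remaining arm sequence 8, the mitochondrial genome 3 and chromosome 4 none. The heterochromatic share was 83.3% (72.1 to 91.4), and 45% of the 20 regions left without unplaced sequence. At 4/3 of the lowest ratio 14 of the 66 regions were left. Of the 66 regions, 64 (97.0%, 89.5 to 99.6) overlapped a dH1 RNAi region, against a mean of 3.70 in the shuffles. None overlapped a WT region (0 of 66, upper limit 5.44%), and the shuffles gave a mean of 0.141 and a highest value of 3, so that random placement also gives about 0. The direct and dH1 RNAi lists share the dH1 RNAi ChIP library, so part of their overlap may come from that library.

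As counted, none of the nuclear directly called regions had more reads in the dH1 RNAi ChIP than in the WT ChIP. The ratio of dH1 RNAi to WT ChIP reads at the 63 nuclear regions had a median of 0.804 (interquartile range 0.744 to 0.921) and lay between 0.710 and 1.00, above the median of 0.434 at the shared regions. The direct regions were called for a high ratio, which sets much of that gap, and with another read extension. At 787351 to 792050 of 3RHet the ratio was 0.879 (0.802 to 0.963), with 877 and 998 reads, and at 3313501 to 3315050 of X it was 0.852 (0.774 to 0.938). At 10051 to 13400 of the mitochondrial genome it was 1.05 (0.918 to 1.19). The dH1 RNAi regions they overlapped had a median of 575 input reads, and 60 of 64 had more than 200.

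Regions were counted in windows of 3 piRNA clusters, which hold transposon remnants and give rise to small RNAs that silence transposons, and the counts were not tested against the length of the lists. In the window of the flamenco cluster on X there were 7 dH1 RNAi regions and 1 WT region, in that of the 38C cluster on 2L 4 and 0, and in that of the 42AB cluster on 2R 2 and 0. The direct list held 2 regions in the 38C window, 1 in the 42AB window and 0 in the flamenco window. The WT region of the flamenco window, at 21500751 to 21502150 of X, had a ratio of 4.69 (3.48 to 6.41) and was shared, with 85 ChIP and 22 input reads after dH1 RNAi, a ratio of 3.86. Of the 13 dH1 RNAi regions of these windows the other 12 had more than 200 input reads and ratios of 0.516 to 0.668, as at 20179401 to 20184000 of 2L, with 561 ChIP and 840 input reads. The histone gene cluster held 2 dH1 RNAi regions and the bithorax complex of Hox genes 1, with no WT region in either, and the Antennapedia complex held none in any list.

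**Figure D4:**
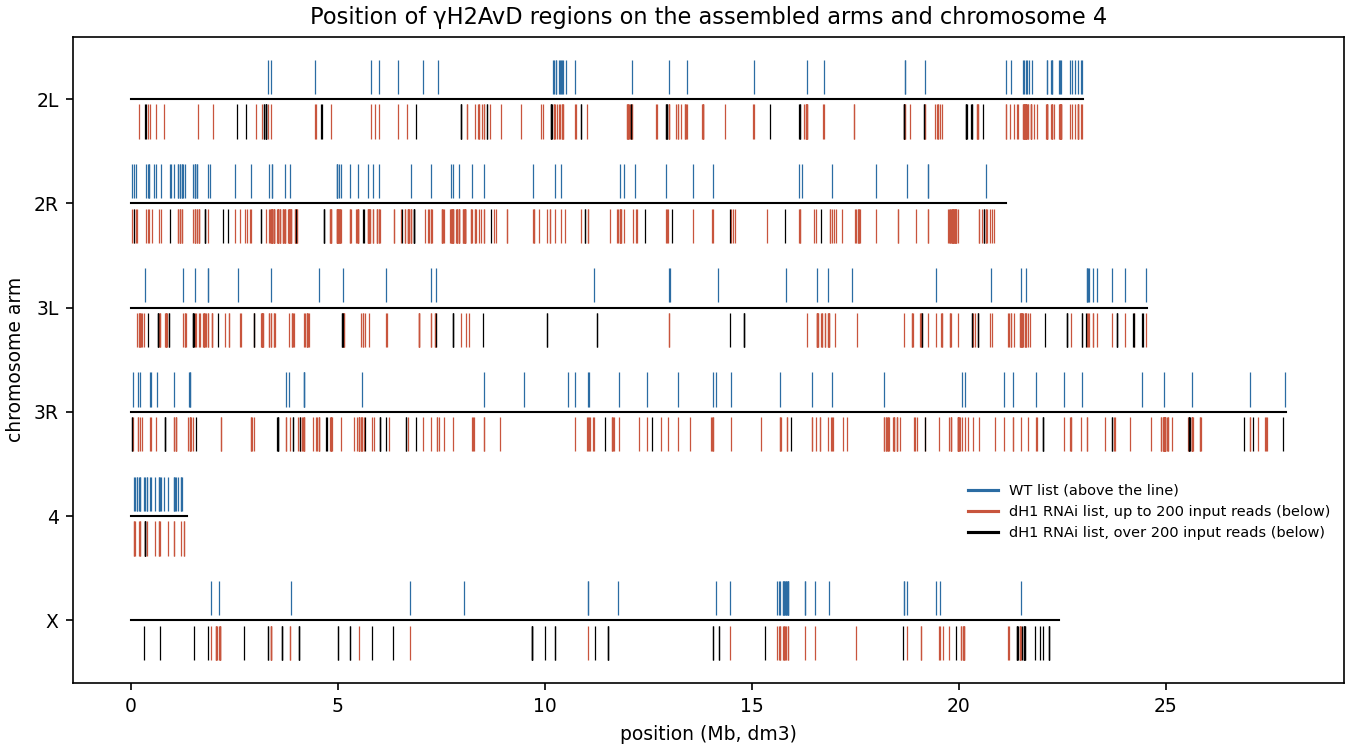
Position in Mb (horizontal axis, dm3) of γH2AvD regions on the 5 assembled arms and chromosome 4. WT regions are drawn above each line and dH1 RNAi regions below it, in black where they had more than 200 input reads. WT regions gather on chromosome 4, near the centromeric ends and between 15 and 16 Mb of X.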

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

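The limits on control reads, the addition of the 3 regions above the FDR cut-off, the removal of the mitochondrial genome and the stricter pairing of shared regions were chosen after seeing the data; the other alternatives were set before the data were examined. No paired analysis was possible because each group has 1 library. Of 142 alternative values, 88 stayed, 44 moved, 9 reversed and 1 came past the threshold. A number of regions, its ratio between the lists or a covered length counted as moved when it changed by over 1.5 times, a share or a median when it left its 95% interval, and the share difference by its sign and its test. Where the number of regions was recomputed, the dH1 RNAi list stayed the longer one, which the minimum at the list median cannot test since it removes about the same share of each list. The ratio thresholds cannot test it at a common ratio either. They were multiples of the lowest ratio of each list, 1.10 in the WT list and 0.446, at a mitochondrial region, in the dH1 RNAi list. Depth is unknown. The cause of these changes was not tested, apart from the regions each alternative removes or joins.

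The heterochromatic share of dH1 RNAi minus WT regions, 0.717 points as reported, reversed under most alternatives. It was -7.48, -17.3 and -17.1 points at ratio thresholds of 4/3, 5/3 and 10/3 of the lowest ratio, -17.1 without unplaced sequence, -5.95 with a proximal length of 2 Mb (p = 0.0621, Fisher's exact test, the only reversal not past the threshold) and -11.1 for as many top-ratio dH1 RNAi regions as WT regions. It was -20.6, -17.8 and -12.2 points at up to 150, 200 and 300 control reads, and 9.37 points, past the threshold, when regions under 10 kb apart were merged. By covered base pairs the shares were 38.5% in the WT list and 37.2% in the dH1 RNAi list.

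At a ratio threshold of 4/3 the dH1 RNAi heterochromatic share was 26.9%, 16.8% of dH1 RNAi regions overlapped WT regions, and the direct list kept 14 regions over 34.1 kb, of which 71.4% overlapped dH1 RNAi regions. At 5/3 the dH1 RNAi list held 1019 regions over 1075 kb, 19.4% of them heterochromatic and 16.6% overlapping WT regions. At 10/3 the WT list held 86 regions over 114.8 kb (57.0% heterochromatic) and the dH1 RNAi list 133 over 171.4 kb (39.9%), 1.55 times as many. No directly called region was left at 5/3 or 10/3.

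Without unplaced sequence the dH1 RNAi heterochromatic share was 14.5%, 17.5% of dH1 RNAi regions overlapped WT regions, and the direct list held 20 regions over 39.9 kb, 45% of them heterochromatic. With ChIP counts of at least the list median, 149 WT, 787 dH1 RNAi and 34 directly called regions were left. Merging under 10 kb gave 1031 dH1 RNAi regions, 42.2% heterochromatic, with a median width of 1100 bp, and merging under 1 kb gave a median width of 1000 bp. Weighted by width, the median WT ratio in the remaining arm sequence was 2.64. The median ratios of shared regions stayed under the stricter pairing. The heterochromatic shares of the WT and dH1 RNAi lists were 28.6% and 32.2% with a proximal length of 0.5 Mb, and 46.1% and 40.2% with 2 Mb. The top-ratio dH1 RNAi regions had a share of 23.2%. With overlap of at least 50% of each region, 64.7% of WT regions and 66.7% of directly called regions overlapped dH1 RNAi regions.

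At up to 150, 200 and 300 control reads the dH1 RNAi heterochromatic share was 13.4%, 15.7% and 21.1%. The first pair of these limits left 887 and 970 dH1 RNAi regions, 3.21 and 3.34 times the WT number, and at 200 reads 21.3% of dH1 RNAi regions overlapped WT regions.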

Other observations

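The windows described here and all tests but that of a lower bar over the input were chosen after the results were seen. Along the arms, more than 10 WT regions lay in 5 windows of 1 Mb: 17 between 1 and 2 Mb of 2R, of which 13 were shared with the dH1 RNAi list, 14 between 22 and 23 Mb of 2L, all shared, 14 between 15 and 16 Mb of X, of which 10 were shared, 12 in the first 1 Mb of 2R, of which 9 were shared, and 11 between 10 and 11 Mb of 2L, of which 5 were shared. The dH1 RNAi windows with the most regions held 51 between 3 and 4 Mb of 2R, 33 between 5 and 6 Mb of 2R and 30 between 22 and 23 Mb of 2L, of which 5, 3 and 15 were shared. The WT list held 5 and 6 regions in the first pair of these windows. Their dH1 RNAi regions had a median of 140 and 122 input reads, against 103 over the remaining arm sequence, and 3 and 2 of them had more than 200. On chromosome 4 the WT regions ran from 63851 to 1234900.

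The dH1 RNAi list held 1563 regions against 297. A lower bar over the input in the dH1 RNAi call was tested with the line of ChIP on input reads above which 95% of WT regions lay: of the 1349 regions seen only in the dH1 RNAi list, 68.3% lay above it after scaling at the shared regions and 0 as counted, so without library totals a lower bar and a gain of the mark cannot be told apart. After scaling, 751 of 761 such regions with at most 200 input reads (98.7%) and 171 of 588 with more (29.1%) lay above it. That scaling takes the mark as unchanged at the shared regions. The regions were also called for ChIP reads over input, so these shares cannot decide. Background in repeated sequence is a candidate explanation for regions with over 200 input reads. Of 588 such nuclear regions, 227 (38.6%) had a ratio at or below the highest of the mitochondrial genome, which carries no histone, and the others lay above it. The mitochondrial regions had 885 to 1063 input reads and most of these nuclear regions had fewer, so that share is not matched for input reads and cannot decide. Background and an effect of dH1 depletion, which was not tested, both stay open: the 6 nuclear regions with as many input reads as the mitochondrial genome (at least 885) had a median ratio of 0.541 and an upper quartile of 0.712, with 4 inside the mitochondrial range of 0.446 to 0.555, which met what had been recorded for background, and were judged too few only by a minimum of 10 set after this value was seen.

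The direct list included the mitochondrial genome, with ratios of dH1 RNAi to WT ChIP reads of 0.816 to 1.05 at 3 regions. The 63 nuclear regions had a median of 0.804, with 0 above the highest mitochondrial ratio and 33 below the lowest. This met what had been recorded for DNA without the mark taking a larger part of the dH1 RNAi ChIP library. The mitochondrial and nuclear regions were all called for a high ratio, however, so their comparison cannot decide, and that explanation stays open. A ceiling on the reads counted per region stays open: the 215 shared regions had a median of 0.434 and an upper quartile of 0.503, below the lowest direct ratio of 0.710 as recorded for the case of no ceiling, but the direct regions were called for a high ratio, which sets much of that gap. The 6 shared regions with at least 558 WT ChIP reads, the median of the nuclear direct regions, had a median of 0.420 and a highest value of 0.623, but were judged too few to decide by the minimum of 10, applied here after the values were seen. A gain of the mark at repeats after dH1 RNAi stays open as an untested alternative.

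On X, 14 WT regions lay between 15 and 16 Mb, from 15597451 to 15886550, and 10 of them were shared. Even placement of separate regions along the arms was argued against. With the list itself counted among 10000 random placements, a share of 0.0002 had as many in any 1 Mb window outside the proximal sequence. The median highest window was 7. The window between 1 and 2 Mb of 2R, with 17 regions, lay above that median too, so this result is not particular to X. A gain in copy number of that part of X may contribute: the median WT input count was 86.5 at these regions and 68 at the other 20 regions of X, a ratio of 1.27 (95% bootstrap interval 0.951 to 1.53). That interval reaches both no gain and a gain of 1.5 times, so copy number stays open, and no biological explanation was tested.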
